A study of Homo sapiens with 6 samples.

How the data were processed

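ChIP-seq was done for H3K4me2 and H3K4me3 in K562 cells with a control hairpin or a hairpin against Staufen 2, with 1 library per mark and hairpin and 1 input library per hairpin. Groups were taken from the sample titles. The input libraries were used only through the peak calls made against them.

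Per the submitters' processing notes, reads were aligned with Bowtie2, whose version is not given in the sources used here, to build hg38, and peaks were called with MACS2. Per the file headers, MACS2 version 2.1.2 was run on each library separately, against the input of the same hairpin, with a q-value threshold of 0.05, no model building, a fragment length of 200 bases, tags of 76 bases, an effective genome size of 2.70e+09, 1 tag kept per position and narrow peaks. The larger data set was scaled to the smaller, per the file headers. The deposited lists give, for each peak, the signal as pileup at its summit, the fold enrichment as the ratio of that pileup to the local background, and the −log10 of the p-value and the q-value. The deposited peak width is the end minus the start plus 1. No spike-in is named in the sources used here, so a difference in overall enrichment has no outside scale.

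Both H3K4me2 lists stop at the last row that a legacy spreadsheet can hold, with 65507 peaks each, and are sorted by chromosome name. The shControl list ends on chromosome 6 at 27590792 and the shStau2 list on chromosome 4 at 185623562. H3K4me2 was therefore compared only on the 16 chromosomes that come wholly before that point and on chromosome 4 up to it, which holds 14728 protein-coding genes. Peaks beyond it were not used in a comparison. The H3K4me3 lists held 22280 peaks under shControl and 27577 under shStau2 and were compared on chromosomes 1 to 22 and X.

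Gene coordinates came from the RefSeq gene table of assembly GRCh38.p14, the same build as the peaks. It holds 19974 protein-coding genes on these chromosomes but no strand and no transcripts. The design fixed before the data were examined asked for windows around the transcription start, and these were replaced by windows of 1 kb on each side of both annotated gene ends. A gained or lost gene can thus have its peak at the 3′ end. Of 38699 such windows, 22.7% overlap a window of another protein-coding gene. Covered bases are the bases within 2 kb of either gene end that peaks cover.

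Peaks were called shared when they overlapped by 1 base or more. Shares carry exact Clopper-Pearson 95% intervals from scipy, and the matched difference of shares of missing H3K4me2 peaks a normal approximation weighted over fold and width groups. Peaks that overlapped exactly 1 peak of the other list, both ways, were used to compare widths and the authors' fold enrichment. With 1 library per group no test between hairpins was run, and values describe these libraries. The depth of each library is the number of tags the file headers give after duplicate removal, from 26221869 to 30744332 for the ChIP libraries. Weak peaks near the threshold are the least certain calls at this depth.

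The 22 gene lists were fixed before the data were examined, and all symbols matched the gene table, giving 483 list entries. The list of genes deleted at 9p21 was not analysed for H3K4me2, since chromosome 9 is outside the compared region. For each list, the gained minus lost count and the summed covered-base difference were given as the percentile among 10000 random lists of the same size, drawn to match in shControl covered bases (0, then 5 equal bins). The rule for named genes, also fixed before, took KDM1A and STAU2, the 6 gained and the 6 lost genes of highest fold enrichment, the 3 largest increases and decreases of covered bases, and up to 4 gained and 4 lost members of each list. Some genes taken by this rule are not reported here. Other genes were named after their values were seen, as examples of list members marked in both lists or as said beside them.

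Overlap and percentiles were tested on data simulated from the shControl H3K4me3 list. Of the peaks planted in both lists or in 1 list only, 100% were recovered as such, and 100% of the peaks left out were found as lost. Planted peaks were moved little or placed far from other peaks, so this checks the code only. Of random lists scored on random normal values per gene, 5.5% fell outside the central 95%. The sparse gained minus lost counts were not calibrated in this way. Overlap counts differed from those of bedtools 2.31.1 by 0 peaks. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

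Alternatives fixed before the data were examined were a −log10 q of 10 or more, a fold enrichment of 5 or more, equal numbers of peaks in both lists, peaks within 1 kb merged, all contigs, 50% reciprocal overlap, windows of 0.5, 2.5 and 5 kb, a peak at or above its list's median fold enrichment, and matching of random lists on the mean of both libraries. Alternatives chosen after the data were seen were a shStau2 threshold raised by the ratio of median fold enrichments at matched peaks, with the lowest 5% of the shControl list by fold enrichment left out, gene ends not shared with another gene, the whole gene with 1 kb on each side, and only peaks that overlap no peak of the other list.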

Results

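Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map dimethylation and trimethylation of lysine 4 of histone H3 (H3K4me2 and H3K4me3) in K562 cells, an established human leukaemia line from blast crisis chronic myeloid leukaemia that carries the BCR-ABL1 fusion. Cells expressed either a control short hairpin RNA (shControl) or a hairpin against Staufen 2 (shStau2), a double-stranded RNA-binding protein encoded by STAU2. H3K4me3 is found mainly at active gene starts, and H3K4me2 at gene starts and enhancers. The series asked how loss of Staufen 2 affects these marks. Each mark was profiled in 1 library per hairpin, and 1 input library per hairpin served as background, giving 6 libraries in all. There were no replicates, so no difference below has a test or a spread between replicates. Intervals printed with shares are exact Clopper-Pearson 95% intervals and cover counting error only.

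After removal of duplicate tags, the H3K4me3 libraries held 30744332 tags under shControl and 26320758 under shStau2, a ratio of 0.856. The H3K4me2 libraries held 26221869 and 27979370 tags, and the inputs 18826946 and 19921064. Duplicates made up 7.0% of the H3K4me3 tags under shControl and 13.0% under shStau2, and 6.0% and 8.0% of the H3K4me2 tags. H3K4me3 was compared on chromosomes 1 to 22 and X. Both H3K4me2 lists stop before the end of the genome, so H3K4me2 was compared only on 16 whole chromosomes and on chromosome 4 up to position 185623562. Fold enrichment is the authors' own value for each peak, and values of both lists are set side by side without a claim of change.

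The gene targeted by the hairpin, STAU2, carried H3K4me3 in both lists. It lies on chromosome 8 at 73420369 to 73747480 (hg38), and its strongest end peak spanned 73745557 to 73746901 under shControl, with a fold enrichment of 34.3. Under shStau2 that peak spanned 73745425 to 73748131, with a fold enrichment of 57.7. A hairpin acts on the mRNA, so a mark at the STAU2 gene does not check the knockdown. KDM1A, which encodes LSD1, the demethylase of mono- and dimethylated H3K4, lies on chromosome 1 at 23019468 to 23083689. KDM1A carried both marks in both lists. Its H3K4me3 peaks covered 2880 bases within 2 kb of the gene ends under shControl and 2914 under shStau2, and its H3K4me2 peaks covered 2838 and 3070. The fold enrichment of its strongest H3K4me3 peak was 27.4 under shControl and 67.7 under shStau2. At 15552 H3K4me3 peaks matched 1 to 1 across the genome, the median rose from 14.99 to 30.97, a ratio of 2.07. Higher values at STAU2 and KDM1A are therefore not particular to these genes.

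H3K4me3 was listed at more sites under shStau2. The added sites included genes of several lineage lists, none of which lay above the central 95% of random lists for net gain in every setting tried. ALAS2, the erythroid enzyme that starts haem synthesis, gained a peak of 8.66-fold enrichment. CD33, a myeloid surface receptor, gained one of 10.2-fold, and CD44, a hyaluronan receptor used as a stem cell marker, gained one of 9.27-fold. Gained means that a peak lay within 1 kb of either annotated end of a gene in the shStau2 list only, and lost means the same in the shControl list only. The strand of each gene was not known, so such a peak need not lie at the gene start. Of 19974 protein-coding genes, 12076 carried H3K4me3 in both lists, 777 gained it, 14 lost it and 7107 had none.

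The shStau2 list held 27333 H3K4me3 peaks over 36.15 Mb, and the shControl list 22041 peaks over 26.43 Mb, ratios of 1.24 and 1.37. Of the shControl peaks, 98.9% (98.8 to 99.1) overlapped a shStau2 peak by at least 1 base, whereas 68.0% (67.4 to 68.5) of shStau2 peaks overlapped a shControl peak. That left 236 peaks in the shControl list only and 8758 in the shStau2 list only. The latter were narrow and weak, with a median width of 321 bases and a median fold enrichment of 5.30, against 1573 bases and 33.1 for shared peaks in the same list. They also lay away from gene ends. Gene ends held 13.7% (13.0 to 14.5) of them, gene interiors 37.6% (36.6 to 38.6) and intergenic sequence 48.7% (47.6 to 49.7), whereas gene ends held 60.5% (59.7 to 61.2) of the shared shStau2 peaks. With windows of 2.5 kb, gene ends held 22.3% of the shStau2-only peaks. The shControl-only peaks were narrow and weak too, with medians of 247 bases and 4.05-fold. With windows of 1 kb, gene ends held 12.7% (8.7 to 17.6) of the shControl-only peaks.

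At 15552 peaks that matched 1 to 1 between the lists, the median fold enrichment was 14.99 under shControl and 30.97 under shStau2, a ratio of 2.07. With the shControl list held to a fold enrichment of 3.97 or more, which leaves out its lowest 5%, and the shStau2 threshold raised by that ratio, to 8.2, the excess ended. Both are meant by the raised threshold below. Then 1084 peaks were in the shStau2 list only and 1578 in the shControl list only, and 190 genes gained and 211 lost H3K4me3. Of the 777 gained genes, 156 were gained at the raised threshold too.

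**Figure D1:**
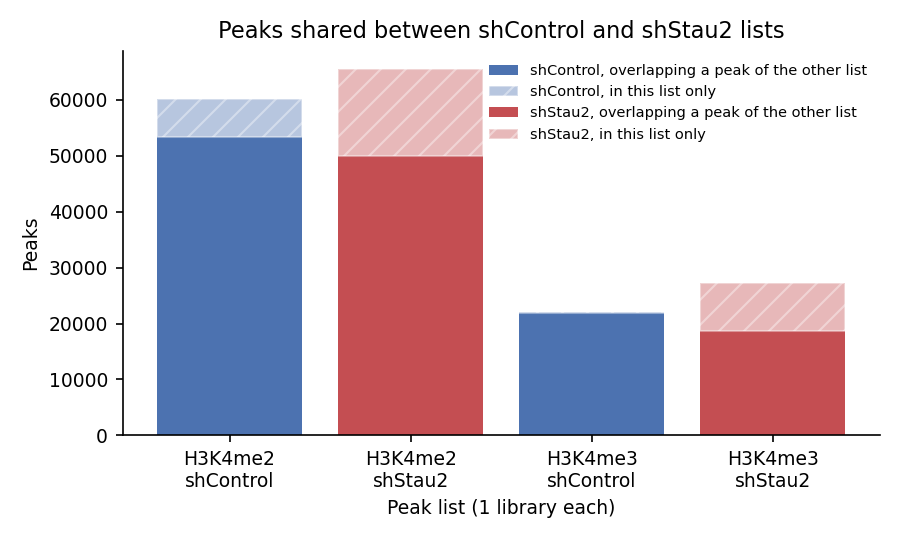
Bars give the number of peaks in each of the 4 peak lists, 1 library each, split into peaks that overlap a peak of the other hairpin's list (solid) and peaks in that list only (hatched). The shStau2 H3K4me3 list holds 8758 peaks of its own and the shControl H3K4me3 list 236.

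Among the 30 erythroid genes, 23 carried H3K4me3 in both lists, 3 gained it and 0 lost it. Beside ALAS2 on chromosome X, the gained genes were HBE1, the embryonic beta-like globin, with a fold enrichment of 5.58, and AHSP, the chaperone of free alpha globin, with 5.49. The ALAS2 peak lay at the higher end of the gene, and the HBE1 peak reached the windows of both ends. The AHSP peak, at 31529518 to 31529935, lay wholly beyond the higher end of the gene at 31528803. The net gain of the erythroid list lay at the 98.7 percentile of 10000 random lists matched on shControl coverage. It was inside the central 95% at 81.6 when both lists were held to equal numbers of peaks, at 95.6 when matched on the mean of both libraries, and at 93.0 with the raised threshold. HBG1, HBG2, HBA1, KLF1 and GATA1 carried H3K4me3 in both lists.

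Among 37 genes of granulocyte and monocyte differentiation, 9 carried H3K4me3 in both lists and 5 gained it, at the 94.4 percentile. CD33 on chromosome 19, IRF5 (an interferon regulatory factor, 4.01-fold, named after its value was seen) and LYZ (lysozyme, 4.14-fold) gained peaks that were absent from the shControl list. At EGR2, an early growth response factor, a peak of 43.0-fold enrichment that overlapped shControl peaks reached the window, and covered bases within 2 kb were 724 under shControl and 1086 under shStau2. SPI1 and CEBPA, the master regulators of myeloid fate, carried H3K4me3 in both lists. The 20 megakaryocyte and platelet genes had 6 members with H3K4me3 in both lists and 0 gained or lost.

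In the list of 22 stem cell and leukaemia self-renewal genes, HOXA9 and CD44 gained H3K4me3 and 15 carried it in both lists. The net gain lay at the 91.3 percentile, inside the central 95%, and above that range only with the raised threshold. It was 66.7 with windows of 2.5 kb and 69.9 with gene ends not shared with another gene. It was 71.3 when matched on the mean of both libraries and 96.8 with equal numbers of peaks. The HOXA9 peak lay on chromosome 7 at 27160551 to 27161636, at the lower end of the gene, with a fold enrichment of 14.2. It overlapped a shControl peak outside the window. The window is shared with the HOXA10-HOXA9 readthrough gene, and shControl peaks already covered 365 bases within 2 kb of the HOXA9 ends. Covered bases were more under shStau2 at 17 of the 22 genes and fewer at 0. MYC had 3178 covered bases under shControl and 3649 under shStau2, MEIS1 had 3499 and 4922, and MYB had 3053 and 3137. The mean difference of 413 bases lay at the 98.8 percentile of matched lists, and at 97.4, inside the central 95%, when random lists were matched on the mean of both libraries.

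The 39 genes of the HOX clusters, which pattern the body axis, had 6 gained genes and 1 lost. HOXA13 (5.63-fold) and HOXD10 (5.38-fold) were among those that gained peaks, and HOXC8 lost one of 4.77-fold, where a shStau2 peak overlapped it outside the window and covered bases were 311 under shControl and 716 under shStau2. Covered bases were more under shStau2 at 26 HOX genes and fewer at 0, which placed the list above the central 95% of random lists, and at the 72.6 percentile with the raised threshold. HOX windows overlap each other, so their members are not independent.

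Members of other lists gained H3K4me3 as well. IFIT3 (8.05-fold) and OAS2 (5.12-fold) were gained among 25 interferon-stimulated genes, HLA-DPA1 (4.10-fold) among 20 antigen presentation genes, and IL1A (3.09-fold) among 20 NF-kB and inflammatory genes. BCL11B (7.74-fold) and CCR7 (6.82-fold) were gained among 20 T cell genes (65.1 percentile), BANK1 (6.84-fold) and BLK (4.75-fold) among 15 B cell genes (77.2 percentile), and TWIST1 (5.60-fold) among 16 fibroblast and mesenchymal genes. The covered-base difference of the fibroblast and mesenchymal list lay at the 97.9 percentile, and at 74.1 when both lists were held to equal numbers of peaks. The 25 neuronal and 15 hepatocyte genes had 0 gained and 0 lost. None was gained or lost among 18 LSD1 complex genes, 19 H3K4 methyltransferase genes, 8 H3K4 demethylase genes, 16 RNA-binding protein genes, 24 BCR-ABL1 signalling genes, 25 cell cycle genes, 20 p53 and apoptosis genes and 36 ribosomal protein genes. The 13 genes deleted at 9p21 in K562, CDKN2A and MTAP among them, had no H3K4me3 peak in either list. Of 22 gained list members named by the fixed rule, 5 were gained at the raised threshold too: ALAS2, EGR2, CD33, HOXA9 and CD44.

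**Figure D2:**
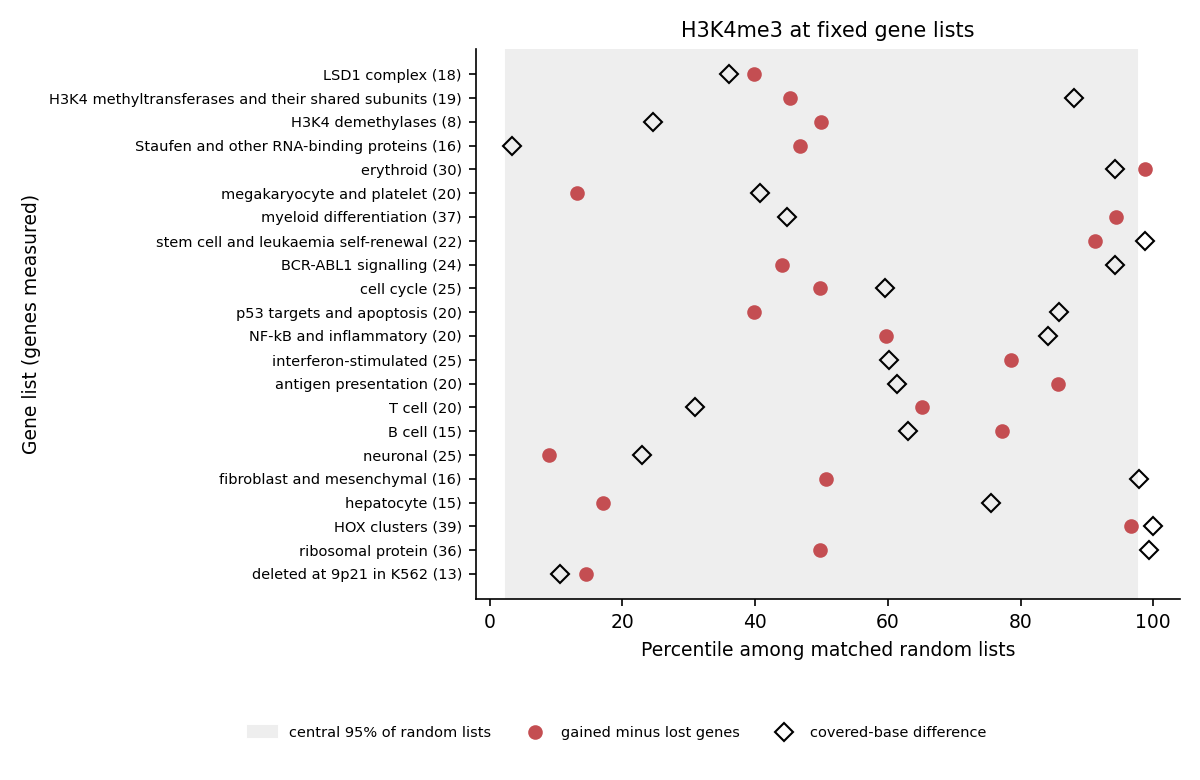
For each gene list (number of genes measured in parentheses), the x axis gives the percentile among matched random lists of the net H3K4me3 gain (filled circles) and of the covered-base difference, shStau2 minus shControl (open diamonds), with the central 95% shaded. The erythroid list stands at 98.7 for net gain, and the HOX list at the right edge for covered bases.

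The gained genes of highest fold enrichment sat at window edges. KPNA7 (72.2-fold, peak shared with SMURF1), NADK (70.9-fold), MYBPC1 (69.5-fold, shared with CHPT1), TSGA10IP (68.5-fold, shared with SART1), NICOL1 (62.5-fold) and ACER1 (60.0-fold, shared with CLPP) led by the fixed rule. At each, the shStau2 peak overlapped shControl peaks and reached past them across the edge. At KPNA7 covered bases within 2 kb were 964 under shControl and 1060 under shStau2. Among all 777 gained genes, 722 had a peak that overlapped no shControl peak. The strongest of these, named after their values were seen, were CES3, a carboxylesterase (16.9-fold), PTX3, a secreted pattern recognition protein (16.3-fold), and SPNS2, a sphingosine 1-phosphate transporter (14.5-fold).

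Few genes lost H3K4me3. RHBDF1 led with a peak of 48.1-fold enrichment shared with MPG, again at a window edge, with 1026 covered bases under shControl and 965 under shStau2. SLC8A2, a sodium and calcium exchanger (6.30-fold), ARSI, an arylsulfatase (6.04-fold), HMX2, a homeobox factor (5.28-fold), ADCY4, an adenylate cyclase (5.02-fold), and NPFFR1, a neuropeptide receptor (4.95-fold), followed. At SLC8A2, ARSI, HMX2 and NPFFR1 covered bases were 0 under shStau2, whereas ADCY4 had 236, in a peak that overlapped the shControl peak outside the window.

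H3K4me3 domains were wider at most marked genes under shStau2. Of the 12076 genes with H3K4me3 in both lists, 11724 (97.1%) had more covered bases and 317 had fewer, with means of 1924 bases under shControl and 2296 under shStau2. The largest increases were at MRPL34, a mitochondrial ribosomal protein gene (2362 to 5119 bases), SPIN4, a spindlin family gene (1340 to 4068), and BTG1, an antiproliferative gene (4878 to 7568). The largest decreases were at SCRT2, a neural repressor (1692 to 734 bases), HMGN2, a nucleosome-binding protein gene (2921 to 2510), and CD164, a sialomucin gene (3420 to 3023). Ribosomal protein genes had a mean difference of 497 bases, at the 99.3 percentile, and 34 of 36 had more covered bases. Matched on the mean of both libraries the list lay at 95.4, inside the central 95%. Covered bases grow with the enrichment over background, which differed between the lists as given above.

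**Figure D3:**
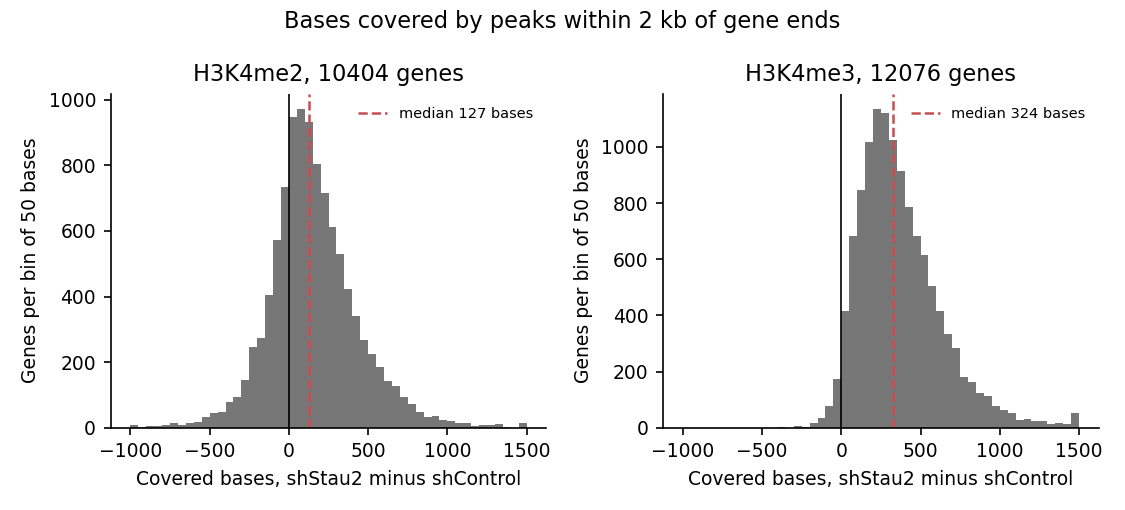
Histograms of the difference in bases covered by peaks within 2 kb of gene ends, shStau2 minus shControl, for genes with a peak in both lists (bins of 50 bases, outer bins hold all values beyond the axis). The medians are 127 bases for H3K4me2 over 10404 genes and 324 bases for H3K4me3 over 12076 genes.

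H3K4me2 was both gained and lost at blood cell genes. Among myeloid genes, NCF4, a subunit of the phagocyte oxidase (7.59-fold), ITGAM, the integrin alpha M chain (4.37-fold), and ELANE, neutrophil elastase (11.1-fold), gained H3K4me2, and ITGB2, the integrin beta 2 chain that pairs with ITGAM, lost a peak of 3.12-fold. CD34, the stem and progenitor surface marker, lost a peak of 4.67-fold on chromosome 1. Covered bases within 2 kb were 651 under shControl and 264 under shStau2 at CD34, and 828 and 376 at ITGB2. Among the gained genes they were 460 and 813 at ITGAM, 510 and 852 at ELANE, and 0 and 731 at NCF4. Of 14728 protein-coding genes in the compared region, 10404 carried H3K4me2 in both lists, 373 gained it, 102 lost it and 3849 had none.

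The compared region held 60090 H3K4me2 peaks over 57.14 Mb under shControl and 65507 over 65.43 Mb under shStau2, ratios of 1.09 and 1.15. Of the shControl peaks 88.8% (88.6 to 89.1) overlapped a shStau2 peak, and of the shStau2 peaks 76.3% (76.0 to 76.6) overlapped a shControl peak, which left 6718 and 15524 peaks in 1 list only. Gene ends held 5.5% (5.1 to 5.9) of the shStau2-only peaks, 5.0% (4.5 to 5.5) of the shControl-only peaks and 27.8% (27.4 to 28.2) of the shared shStau2 peaks. At 40029 peaks matched 1 to 1, the median fold enrichment was 7.03 under shControl and 8.46 under shStau2, a ratio of 1.2. With the lists held to fold enrichments of at least 3.3 (shControl) and 3.97 (shStau2), 304 genes gained and 154 lost H3K4me2, and 283 of the 373 gained genes were among the 304.

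Few members of each list gained or lost H3K4me2. HBE1 (3.48-fold) was gained among 23 erythroid genes and GP5, a platelet glycoprotein (10.04-fold), among 19 megakaryocyte genes. The peaks at GP5 and ELANE overlapped shControl peaks that lay outside the window. Among 29 myeloid genes 3 were gained and 1 was lost, at the 86.8 percentile, and among 14 stem cell genes only CD34 was lost, at the 3.7 percentile. LCK, a T cell kinase (5.15-fold), and CD2, an adhesion receptor (4.23-fold), were gained among 17 T cell genes, and FAS, the death receptor (6.44-fold), among 17 p53 and apoptosis genes. The FAS peak lay at the higher end of the gene. The neuronal genes CELF4 (2.91-fold) and GAP43 (2.71-fold) were gained among 17. In the HOX clusters HOXD9 (4.37-fold) and the pair HOXD3 and HOXD4, which share a peak of 4.66-fold, were gained, and HOXB1 lost a peak of 2.55-fold. The net gain of the HOX list lay at the 95.8 percentile. It lay at 99.6 with the raised threshold and at 40.1 with gene ends not shared with another gene. At the raised threshold the gains at HBE1, CELF4 and GAP43 ended, and the lost peaks of ITGB2 and HOXB1 were left out with the lowest shControl peaks. The LSD1 complex, methyltransferase, demethylase, RNA-binding protein, BCR-ABL1 signalling, cell cycle, inflammatory, interferon, antigen presentation, B cell, fibroblast, hepatocyte and ribosomal protein lists had 0 gained and 0 lost.

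The strongest gained and lost H3K4me2 genes were mostly edge cases. VSIG10L (42.1-fold), CADM4 (30.6-fold, shared with ZNF428), SPX (24.6-fold), ZNF550 (23.4-fold) and CIROP (23.1-fold) gained peaks where shControl peaks already covered between 251 bases (CIROP) and 2197 bases (CADM4) within 2 kb. KIRREL2 (32.9-fold, shared with APLP1), PLCH2 (20.2-fold, shared with PEX10), CIMAP1B (9.59-fold), C13orf42 (7.91-fold) and IL27 (7.07-fold) lost peaks in the same manner. Covered bases were fewer under shStau2 at KIRREL2 (1363 to 966), PLCH2 (1008 to 963) and CIMAP1B (1183 to 981). They were more under shStau2 at C13orf42 (923 to 969) and IL27 (427 to 453). KRT17, a keratin gene, lost its whole peak of 7.03-fold, and its covered bases were 638 under shControl and 0 under shStau2.

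Of the 10404 genes with H3K4me2 in both lists, 7557 (72.6%) had more covered bases under shStau2 and 2768 had fewer, with means of 2544 bases under shControl and 2700 under shStau2. Among the largest increases were UNC5C, a netrin receptor (544 to 2836 bases), and MYCL, a MYC family gene (3601 to 5713). The largest decreases were at SCRT2 (3667 to 1699 bases), SLC27A2, a very long chain acyl-CoA synthetase gene (4577 to 3037), and IFT70B, an intraflagellar transport gene (4179 to 2855). SCRT2 had the largest decrease in both marks. Ribosomal protein genes had a mean difference of 327 bases, at the 99.9 percentile, and the LSD1 complex one of 290 bases, at the 98.0 percentile, which was 96.6 when both lists were held to equal numbers of peaks. Of 86 percentiles computed over both marks 7 lay outside the central 95%, and 4.3 would by chance. All of the 7 but the erythroid net H3K4me3 gain were covered-base percentiles. Net-gain percentiles of lists with few gained or lost members stay near the middle. The 4.3, which treats both measures alike, is thus a rough guide only.

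Gene ends that carried H3K4me2 alone under shControl often carried both marks under shStau2. Of 14728 genes, 9069 had both marks under shControl and 9575 under shStau2, while those with H3K4me2 alone numbered 1437 and 1202, and those with neither 4210 and 3919. Of the 1437 genes with H3K4me2 alone, 468 (32.6%) had both marks under shStau2, and 9 of 9069 genes went from both marks to H3K4me2 alone. With the raised threshold, 124 genes went from H3K4me2 alone to both marks and 153 the other way. Of the 4210 genes with neither mark under shControl, 371 gained H3K4me2, 69 gained H3K4me3 and 45 gained both, where independent gains would give 6.1. Both marks were called against the same input library under each hairpin, so the gains were not independent measurements.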

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

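No test is reported in this part. The shControl H3K4me2 list holds 5417 peaks beyond the point at which the shStau2 H3K4me2 list stops, from chromosome 4 position 185623562 to chromosome 6 position 27592808. They stand out as measured signal that entered no comparison, because shStau2 peaks in that stretch were not analysed here.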

How the results depend on the processing

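The raised shStau2 threshold and the choice of peaks that overlap no peak of the other list were added after the results were seen, as were unshared gene ends and whole genes. No paired analysis was possible because each group has 1 library and no test was run, and leaving out a replicate was not possible either. Any annotated transcript start was not run, since the gene table holds no transcripts, and all contigs was not run for H3K4me2, since contigs sort after the end of the lists. Of 126 counts and differences recomputed, 90 stayed within 1.5 times their value and 36 moved. Some of the 90 could not move, so their number is no measure of stability. Merging peaks leaves the gene calls unchanged, the added contigs hold none of the genes used, and equal numbers of peaks set the list sizes. Most of the 126 are counts, which have no sign to change. Of 26 shares 24 moved outside the interval of the first value. The share of shStau2 H3K4me3 peaks that overlapped a shControl peak was 82.2% with equal numbers of peaks and 93.8% at the raised threshold. With windows of 2.5 kb, gene ends held 11.7% of shStau2-only and 11.2% of shControl-only H3K4me2 peaks, and 22.3% and 20.8% for H3K4me3. Causes were not tested except where the setting itself removes peaks.

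With a −log10 q of 10 or more, H3K4me2 peaks numbered 28633 under shControl and 32814 under shStau2, with 1570 and 6761 in 1 list only and 62 genes lost. H3K4me3 then had 33 shControl-only and 5120 shStau2-only peaks and 3 genes lost, and 1 gene went from both marks to H3K4me2 alone. With a fold enrichment of 5 or more, H3K4me2 peaks numbered 38866 and 43645, with 4044 in the shControl list only. Merging peaks within 1 kb left 4450 H3K4me2 and 155 H3K4me3 peaks in the shControl list only. With 50% reciprocal overlap, 19958 shControl and 25375 shStau2 H3K4me2 peaks and 6208 shControl H3K4me3 peaks were in 1 list only.

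With equal numbers of peaks, 654 shControl and 3929 shStau2 H3K4me3 peaks were in 1 list only, 441 genes gained and 58 lost H3K4me3, 291 went from H3K4me2 alone to both marks and 37 the other way. A peak at or above its list's median fold enrichment left 70 gained and 9 lost genes for H3K4me2, and 46 gained and 1 lost for H3K4me3. Windows of 5 kb gave a mean H3K4me2 covered-base difference of 243 bases over all genes.

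The raised threshold was the only setting that turned the H3K4me3 excess around, with 1084 shStau2-only and 1578 shControl-only peaks, 190 gained and 211 lost genes, and 124 genes that went from H3K4me2 alone to both marks against 153 the other way. It gave 154 lost genes for H3K4me2, and 688 genes with fewer bases covered by H3K4me3. The mean H3K4me3 covered-base difference was 211 bases there, though raising the threshold leaves the width of kept peaks as it was. Of 344 list percentiles recomputed, 14 moved outside the central 95% and 10 moved inside. Only recomputed values of the 7 percentiles that first lay outside could move inside. The 10 are thus a far larger part of those than of the 344. The number of others is no measure of stability. Net-gain percentiles of lists with nearly all members marked in both lists stay near the middle in most settings. The neuronal list's net H3K4me3 gain went from percentile 9.0 to 0 with equal numbers of peaks and with the raised threshold. Its covered-base difference went from 22.9 to 0 with the raised threshold. Depth limits the weak peaks most. Before scaling to the smaller data set, ChIP tags were fewer under shStau2 for H3K4me3 and more for H3K4me2.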

Other observations

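All tests in this part were chosen after the results they bear on were seen. The ZNF zinc finger genes, a family of DNA-binding repressors, gained more new H3K4me3 peaks than matched genes, with 23 of 517 against a mean of 10.4 in random lists, at the 99.96 percentile of 10000 lists. ZNF233 (13.2-fold, chromosome 19) and ZNF597 (12.9-fold, chromosome 16) were the strongest. Olfactory receptor genes had 2 of 392 where random lists averaged 34.8, and the keratin-associated KRTAP genes 0 of 94 where random lists averaged 8.45. Families were grouped by the letters that open the symbol, and 149 with at least 15 genes were looked at. Of these, 5 lay above and 7 below the central 95% for new minus vanished peaks, where 3.7 on each side would by chance, and members of a family often lie side by side, so they are not independent.

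Broad H3K4me3 peaks of at least 4 kb numbered 280 under shControl and 867 under shStau2, and 279 of the latter overlapped a broad shControl peak. Peak width grows with the enrichment over background, which was 2.07-fold higher at matched peaks under shStau2. Of those matched peaks, 95.5% were wider under shStau2. The counts therefore do not show that new broad domains formed. The widest lay over GATA2, a blood stem and progenitor cell factor, on chromosome 3 at 128482499 to 128493525, with 11027 bases under shStau2 of which 10396 were covered under shControl. IGF2BP3, an RNA-binding protein gene, had 10803 bases with 8310 covered under shControl, and NUDT4 had 9529 with 6549. A broad peak over COMMD3 and BMI1, a polycomb gene, had 6974 bases with 4210 covered under shControl. The share of shStau2 H3K4me3 peaks in that list only ranged from 22.5% on chromosome 17 to 40.7% on chromosome 18.

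The larger number of H3K4me3 peaks under shStau2 was weighed against depth and overall enrichment. The shStau2 H3K4me3 library held fewer tags before scaling, with a ratio of 0.856. Peaks were called with the larger data set scaled to the smaller, here the inputs, whose ratio was 1.058. The tag counts therefore do not decide whether depth played a part. Once the threshold was raised by the ratio of medians, 1084 shStau2-only peaks were left, against 1578 shControl-only peaks. The upper quartile of fold enrichment of the shStau2-only peaks was 6.52, below the raised threshold of 8.2. Most of them were thus removed whatever their cause. An even rise of enrichment over background could account for the excess, but the raised threshold does not decide this. Whether such a rise, 2.07-fold at matched peaks, lies in the cells or in the yield of the immunoprecipitation cannot be told apart, because each hairpin has 1 library and no spike-in is named. An effect of the hairpin on H3K4me3 stays open.

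The shStau2-only H3K4me3 peaks lay at sites that carried H3K4me2 under shControl. In the compared region 86.1% (85.2 to 86.9) of them overlapped a shControl H3K4me2 peak, against 7.1% (6.6 to 7.6) of the same peaks moved by 20 kb, which argues against placement without regard to H3K4me2. Shared peaks did so in 98.7%, and H3K4me2 peaks without shControl H3K4me3 held a shStau2 H3K4me3 peak in 3.5% of the weakest and 28.4% of the strongest when ranked by fold enrichment and split into 5 equal groups. Whole H3K4me2 peaks were rarely missing at these sites under shStau2. The share was 0.75% against 6.0% of peaks of like fold enrichment and width without H3K4me3, a difference of -5.25 percentage points (-5.56 to -4.93). The sites were chosen by a shStau2 H3K4me3 peak called against the same input as shStau2 H3K4me2. That choice favours a low share, so the difference does not decide on loss. A fall in level that leaves a peak would not be seen. A weak H3K4me3 signal at strong H3K4me2 sites may have passed the threshold through higher enrichment. At the raised threshold 1084 shStau2-only peaks, counted over all chromosomes, were left. That setting removes weak peaks of any cause, so it does not decide this.

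Genes gained H3K4me3 mostly through new peaks. A neighbouring peak that itself widened into the window is argued against as the main source, since 7.1% of the 777 gained genes had window peaks that all overlapped shControl peaks. Spread as a separate peak beside a shControl peak would count as new. Of all shStau2-only H3K4me3 peaks, 22.3% lay within 2 kb of a shControl H3K4me3 peak. The 7.1% included the gained genes of highest fold enrichment, KPNA7, NADK and MYBPC1 among them, so a ranking by fold enrichment led to widened peaks. New peaks at CES3, PTX3 and SPNS2 remained as sites to look at again in further libraries.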
